A study of Homo sapiens with 8 samples.

How the data were processed

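RNA was profiled by bulk sequencing in 8 libraries of type 2 alveolar cell-like cells derived from the H9 human embryonic stem cell line. The titles put them in 4 groups of 2: untreated monolayer cells titled mono, untreated organoid cells, untreated monolayer cells titled v, and monolayer cells treated with nano carbon black at 100 ng per mL, titled Carbon. The mono and v libraries carry the same labels apart from the title, and the meaning of v is not given in the sources used here. Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

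The deposited table gives FPKM per gene and library, that is fragments scaled to transcript length and to the mapped fragments of the library, per the file headers. Trimmomatic, Bowtie2 2.2.5 and the builds hg38 and GRCh38.p11 are named per the submitters' processing notes, without their roles. The program that counted reads, its strand setting and its treatment of reads shared by near-identical genes are not given in the sources used here. Values of gene families with near-identical copies, such as HLA, metallothionein, HSPA1A, GSTA1, PRSS2, UGT1A6 and ribosomal protein genes, are therefore uncertain. The table states no scaling between libraries beyond FPKM.

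Of 24107 entries, 5986 had no values and were left out, which leaves 18121. Entrez Gene identifiers matched 18076 of these to the RefSeq annotation of GRCh38.p14, used for names only, since the submitters' build differs, and 28 names that a spreadsheet had turned into dates were resolved by identifier. Coordinates are not printed for the same reason. Read counts are not part of the table, so the depth is unknown. Among low values, the most frequent log2 ratio to mono 1 lay between -0.04 and 0 in 6 libraries but at 0.96 in organoid 1, where it rested on 5 of 27 genes, so the relative depth could not be set firmly. FPKM sums ran from 467930 in v 2 to 606471 in organoid 1, and the 20 highest genes held 12.9% to 18.5% of them. Pearson r between the 2 libraries of a group, across genes on the log2 scale, lay between 0.995 and 0.997, and 0.663% to 0.938% of tested genes had identical values, so no pair was treated as one library.

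Genes with an FPKM of at least 1 in at least 2 libraries were tested, 13428 in all. Values were analysed as log2(FPKM + 1), so a log2 change understates the change of low genes. All 8 libraries entered 1 limma fit of 4 groups with 4 residual degrees of freedom, moderated with an intensity trend (limma 3.58.1 in R 4.3.3, prior degrees of freedom 5.005). Tests were two-sided, adjusted by Benjamini-Hochberg over all genes, and called at adjusted p under 0.05. Fitting all groups together lets groups of 2 share 1 estimate of the spread. The comparisons were organoid with mono, Carbon with v, and v with mono. The labels do not say which untreated monolayer set is the control of the treatment. The mono titles were assumed to pair with the organoid titles, so v was taken as the main control. Mono, and mono with v pooled, were alternatives.

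Gene lists, 33 in number, were fixed before the data were examined: AT2, AT1, airway, pan-epithelial, pluripotency, liver and gut, mesenchyme, neural, endothelial and blood markers, lung and foregut progenitor genes, cell cycle, extracellular matrix and TGF-beta, WNT, glucocorticoid, fatty acid, cholesterol, lysosome, aryl hydrocarbon receptor, NRF2, NF-kB, interferon, ER stress, p53, hypoxia and glycolysis, metallothionein, heat shock, immediate early, phagocytosis, mitochondrially encoded, respiratory chain, ribosomal protein and histone genes. Each of the 29 lists with at least 5 tested members was tested with camera in limma at a preset correlation of 0.01, adjusted over the lists. Camera compares a list with all other genes, while fry asks whether its members move one way on balance. No list call in any comparison held with an estimated correlation. Camera then rests on the 4 residual degrees of freedom, which lowers its power, so a lost call does not show that correlation between genes produced it. Glucocorticoid genes in organoid against mono went from adjusted p = 0.00208 to 0.353 in camera. Their estimated correlation, -0.057, lay below the preset one. The mitochondrially encoded list had no member with values.

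The rule for named genes, also fixed before the data were examined, took the 8 largest rises and 8 largest falls (4 and 4 for v with mono) among called genes whose groups did not overlap and whose higher group had a mean FPKM of at least 5. Unnamed loci, pseudogenes, antisense and small RNAs, and genes linked to sex were left out. It also took up to 4 members with the smallest p in each list, and in every comparison SFTPC, SFTPB, NKX2-1, ABCA3, LAMP3, AGER, PDPN, HOPX, CYP1A1, CYP1B1, HMOX1, NQO1, IL6 and CXCL8.

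The calculation was tested for Carbon with v on simulated values of 13428 genes, with the measured means, variances drawn from the fitted prior, and 50 genes changed at each size among genes with a mean log2 value above 2. It recovered 32% of genes changed by 0.3 on the log2 scale, 78% at 0.5, 96% at 1 and 100% at 2, with 7 unchanged genes among 160 calls. Alternatives covered the pseudocount, the filter, median-of-ratios scaling, quantile normalization, TPM conversion, the trend, the groups in the fit, a replicate block, each library left out, a fold threshold, the control set, fry and the estimated correlation.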

Results

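Expression was measured in 8 libraries of alveolar cell-like cells made from H9, an established human embryonic stem cell line. Type 2 alveolar (AT2) cells make lung surfactant, and type 1 (AT1) cells form the thin gas exchange surface. Untreated cells were made in a monolayer (groups mono and v) or in organoids, and monolayer cells were also exposed to nano carbon black, a particle of fine soot, at 100 ng per mL (Carbon). Each group had 2 libraries, so every mean ± SD below is FPKM with n = 2, and log2 changes are given ± SE from limma. The depth behind the FPKM values is unknown. On the first principal component, which held 74.3% of the variance, organoid libraries stood at 66.5 and 65.8, mono at -0.39 and -0.88, Carbon at -21.6 and -26.9 and v at -39.4 and -43.1.

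**Figure D1:**
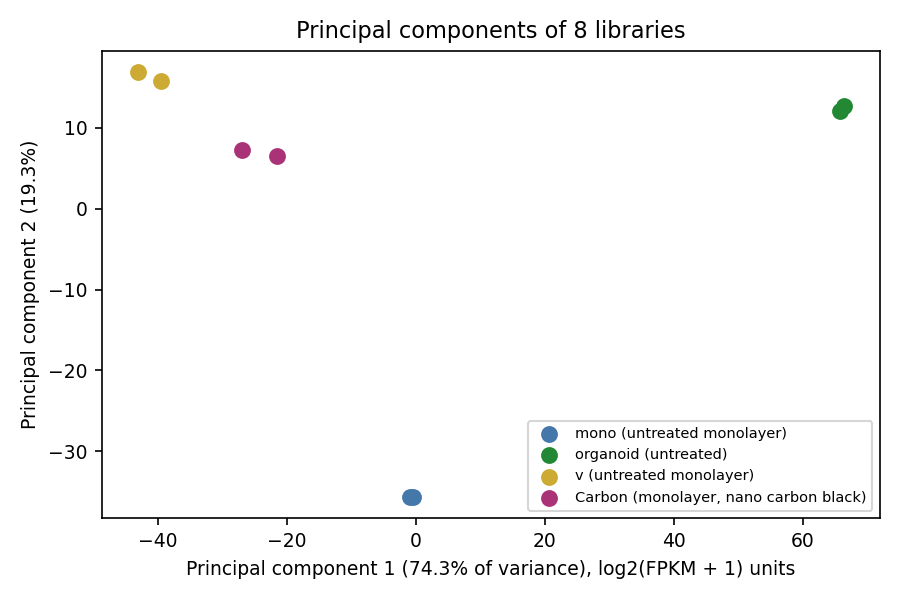
Principal components 1 and 2 of the 8 libraries on log2(FPKM + 1) values, 1 point per library and a colour per group. The 2 libraries of each group lie close together, and the Carbon libraries lie between v and mono on component 1.

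SFTPC, the surfactant protein used as the AT2 marker, was at 0.28 FPKM or below in every library and was not tested. SFTPB, another surfactant protein, was at 3.90 ± 0.00707 in mono, 1.40 ± 0.134 in organoid, 0.475 ± 0.106 in v and 0.54 ± 0.0283 in Carbon. NKX2-1, the lung lineage transcription factor, was at 4.35 ± 0.141 in mono, 1.25 ± 1.03 in organoid, 0.045 ± 0.0354 in v and 0.24 ± 0.0283 in Carbon. ABCA3, the lamellar body lipid transporter, was at 8.97 ± 0.58, 1.83 ± 0.0636, 16.4 ± 0.834 and 13.5 ± 0.629 in the same order.

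**Figure D2:**
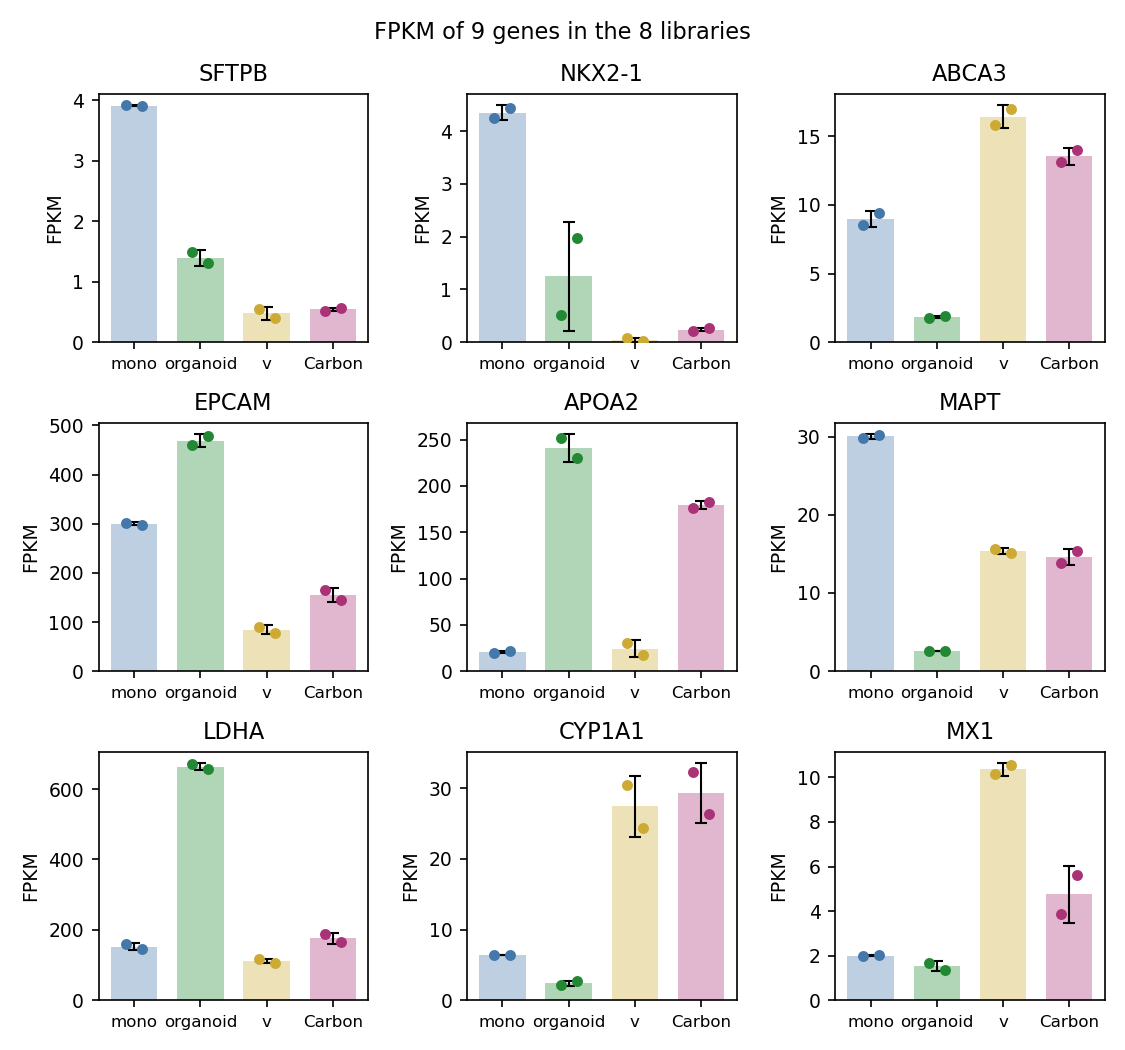
FPKM of 9 genes by group on linear axes that start at 0, with bars for the mean of 2 libraries, error bars for SD and points for libraries. APOA2 stands at 179 in Carbon and 24.3 in v, while CYP1A1 stands at 29.3 and 27.4.

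The first comparison asked how organoid culture differs from monolayer culture without treatment. All 20 cell cycle genes and 15 of 18 hypoxia and glycolysis genes were higher in organoid than in mono, and 13 of 14 neural markers were lower. REG4 (Entrez Gene 83998), a lectin of gut secretory cells, rose from 1.36 ± 0.113 to 57.2 ± 0.29, a log2 change of 4.62 ± 0.25 (adjusted p = 5.35e-07). VGF (7425), a neuroendocrine secreted protein, fell from 195 ± 24.8 to 3.92 ± 0.247, a log2 change of -5.32 ± 0.0898 (adjusted p = 3.74e-09). In all, 9783 of 13428 genes passed, 3272 higher and 6511 lower in organoid, and 1802 of these changed by at least 1 on the log2 scale. The share higher was 33.4%, but 51.1% after median-of-ratios scaling, 50.7% after quantile normalization and 19.8% as TPM. The median over all genes was -0.19, against 0.00 after median-of-ratios scaling and -0.42 as TPM, so small list changes are to be read relative to it.

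Other large rises were those of the gut lectin REG3A (log2 change 4.07, with 28.7 ± 19.5 in organoid), LCN15 (4.02), ANXA10 (3.70), the lipoprotein component APOA2 (3.48), the plasma protein ORM1 (3.31) and AGR2 (3.29), a chaperone of mucus-secreting cells. The largest falls besides VGF were those of APOA4 (-3.72), the secretory granule protein SCG2 (-3.66), HMP19 (-3.49), the airway secretoglobin SCGB3A2 (-3.29), CALB1 (-3.18), PMEL (-3.13) and MAPT (-3.12), which encodes tau. Among neural markers 13 of 14 fell and none rose, DCX from 44.2 ± 0.877 to 5.01 ± 0.205 and STMN2 from 236 ± 7.74 to 38.9 ± 0.0354 (camera adjusted p = 5.78e-05, and adjusted p = 0.365 with an estimated correlation).

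All 20 cell cycle genes rose, among them the replication helicase subunit MCM3 (1.64 ± 0.0678) and RRM2 (1.68 ± 0.0748), with camera adjusted p = 4.68e-12 and adjusted p = 0.365 with an estimated correlation. Of 18 hypoxia and glycolysis genes 15 rose and 1 fell. LDHA, lactate dehydrogenase, went from 151 ± 10.2 to 663 ± 10.1 and ENO1, enolase, from 785 ± 3.54 to 1993 ± 1.81 (list adjusted p = 4.38e-09, and adjusted p = 0.353 with an estimated correlation). With v as the monolayer group 12 hypoxia and glycolysis genes rose and 5 fell, and the list median was 0.23, against 1.14 with mono. Pan-epithelial genes rose in 13 of 16 cases, RAB25 by 1.16 ± 0.1 and KRT19 by 1.10 ± 0.128, while 1 fell (adjusted p = 7.65e-06, and adjusted p = 0.568 with an estimated correlation). NRF2 antioxidant genes rose in 14 and fell in 3 of 19, with NQO1 up by 1.96 ± 0.0697 (adjusted p = 1.19e-05, and adjusted p = 0.374 with an estimated correlation). No NRF2 gene fell without mono 1 or organoid 1. Respiratory chain genes rose in 19 of 20 (adjusted p = 5.82e-08, and adjusted p = 0.365 with an estimated correlation). As TPM 10 of them rose and 1 fell. Ribosomal protein genes also rose in 19 of 20, with RPS6 up by 0.85 ± 0.0636 (adjusted p = 1.12e-08, and adjusted p = 0.45 with an estimated correlation), but their median went from 0.46 to -0.02 after quantile normalization, with 5 rises and 5 falls.

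Fatty acid and phospholipid genes rose in 8 and fell in 4 of 19, PLIN2 of the lipid droplet coat by 1.33 ± 0.061 (adjusted p = 0.0334, and adjusted p = 0.365 with an estimated correlation). Cholesterol synthesis genes rose in 8 and fell in 3 of 17 (adjusted p = 0.0215, and adjusted p = 0.568 with an estimated correlation). As TPM the medians of the fatty acid and cholesterol lists turned to -0.10 and -0.16, with 5 rises and 9 falls in the one and 5 and 8 in the other. After median-of-ratios scaling 13 fatty acid genes rose and 2 fell. Glucocorticoid response genes fell in 11 of 13, TSC22D3 from 134 ± 0.481 to 38.2 ± 2.32 and KLF9 from 6.62 ± 0.191 to 0.295 ± 0.0636 (adjusted p = 0.00208, and adjusted p = 0.353 with an estimated correlation). Matrix and TGF-beta response genes fell in 13 and rose in 1 of 18, with SPARC down by -2.04 ± 0.0548 (adjusted p = 0.0334, and adjusted p = 0.568 with an estimated correlation). With v as the monolayer group the matrix, glucocorticoid and fatty acid calls ended. Matrix genes had 7 rises and 8 falls with a median of -0.20 (adjusted p = 0.437), glucocorticoid genes had 4 and 8 (0.941) and fatty acid genes 7 and 8 (0.308). Leaving out organoid 2 also ended the matrix (adjusted p = 0.0705), fatty acid (0.0512) and cholesterol calls (0.0613).

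AT2 markers rose in 2 (PGC and CLDN18) and fell in 9 of 14, NAPSA by -1.96 ± 0.135, and AT1 markers rose in 4 and fell in 8 of 14, CAV1 by -1.62 ± 0.0917. Neither list passed against all other genes (adjusted p = 0.346 and 0.587). With v in place of mono as the monolayer group, both lists passed as higher in organoid (adjusted p = 0.015 and 0.0297, and adjusted p = 0.393 and 0.429 with an estimated correlation). Members still went both ways, with 9 rises and 4 falls of AT2 markers and 8 and 4 of AT1 markers. Against mono, liver and gut markers went both ways, 8 up and 8 down of 16, with LGALS4 at 526 ± 30.9 against 73.9 ± 0.467 and APOB at 1.94 ± 0.566 against 17.6 ± 0.0848. With v as the monolayer group 10 rose and 2 fell, with a median of 1.03 (adjusted p = 0.000265, and adjusted p = 0.429 with an estimated correlation). Against mono the remaining lists did not pass either. Their rises and falls were 7 and 4 of 14 lung and foregut genes, 5 and 2 of 11 airway genes, 3 and 1 of 5 pluripotency genes, 2 and 9 of 15 mesenchyme genes, 7 and 4 of 14 WNT genes and 3 and 10 of 18 lysosome genes. They were 4 and 2 of 10 aryl hydrocarbon receptor targets, 7 and 7 of 18 NF-kB genes, 1 and 11 of 19 interferon genes, 4 and 10 of 19 ER stress genes, 5 and 11 of 17 p53 targets and 0 and 5 of 6 metallothionein genes. Heat shock genes had 2 and 8 of 12, immediate early genes 4 and 5 of 12 and phagocytosis genes 6 and 5 of 15. Median-of-ratios scaling changed several of these counts, to 7 and 5 for lysosome, 8 and 8 for ER stress, 4 and 4 for heat shock, 5 and 3 for immediate early, 8 and 3 for phagocytosis and 4 and 7 for AT2 genes. Medians turned from 0.06 to -0.16 for liver and gut, 0.06 to -0.10 for airway, 0.02 to -0.16 for aryl hydrocarbon receptor and 0.04 to -0.18 for immediate early genes as TPM. They turned from -0.06 to 0.15 for NF-kB and -0.07 to 0.17 for phagocytosis genes after median-of-ratios scaling. Without organoid 1 the mesenchyme list passed as lower (3 rises and 12 falls, adjusted p = 0.0227), without mono 2 only 1 lysosome gene rose, and without organoid 2 only 3 p53 targets did. With v as the monolayer group 15 lists passed, 14 of them higher in organoid. These included lung and foregut (9 rises and 4 falls, adjusted p = 0.00774), NF-kB (13 and 3, 9.82e-05), immediate early (11 and 1, 4.13e-05) and phagocytosis genes (8 and 2, 0.015). With an estimated correlation the adjusted p of these was 0.429, 0.393, 0.393 and 0.413. Too few members were tested of the endothelial (2), blood (3) and histone (4) lists, of which 1, 2 and 0 rose against mono. Adjusted over the list alone, every count against mono was the same except 20 risen ribosomal protein genes and 1 fallen aryl hydrocarbon receptor target. Median, mean and test against mono differed in sign for the airway, liver and gut, NF-kB and phagocytosis lists.

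The second comparison set the v libraries against mono, as a measure of how far untreated monolayer sets lay apart. All 16 pan-epithelial genes, 13 of 16 liver and gut markers and 15 of 18 NF-kB genes were lower in v, while 14 of 18 hypoxia and glycolysis genes were higher. PGC, a progastricsin also made by AT2 cells, fell from 48.2 ± 1.75 to 0.1 ± 0.0283 (log2 change -5.48 ± 0.144, adjusted p = 4.36e-08), and EPCAM, the epithelial adhesion molecule, from 300 ± 3.18 to 84.4 ± 8.68 (-1.82 ± 0.0811, adjusted p = 4.99e-07). The nuclear receptor NR2F1 rose from 3.87 ± 0.396 to 34.8 ± 1.29 (2.88 ± 0.267, adjusted p = 2.92e-05), followed by GPNMB (2.83), NMRK2 (2.64) and S100A3 (2.61). PRSS2 (-5.36), APOA4 (-4.70) and APOC3 (-4.67) were the other largest falls. Of 13428 genes 7730 passed, 4663 higher and 3067 lower in v. The share higher was 60.3%, against 49.7% after median-of-ratios scaling and 71.0% as TPM, which moved the median over all genes from 0.08 to 0.18.

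All 16 pan-epithelial genes fell (adjusted p = 1.77e-08, and adjusted p = 0.459 with an estimated correlation). Liver and gut markers fell in 13 and rose in 1 of 16, with APOA1 at 30.3 ± 11.8 against 394 ± 17.6 (adjusted p = 1.37e-06, and adjusted p = 0.459 with an estimated correlation). AT2 markers fell in 11 and rose in 3 of 14, with LAMP3 up by 1.52 ± 0.104 and ABCA3 up by 0.81 ± 0.0745 (adjusted p = 7.63e-05, and adjusted p = 0.193 with an estimated correlation). AT1 markers fell in 11 of 14 (adjusted p = 2.32e-06, and adjusted p = 0.201 with an estimated correlation), and lung and foregut genes fell in 9 and rose in 3 of 14 (adjusted p = 0.0127, and adjusted p = 0.462 with an estimated correlation). NF-kB genes fell in 15 and rose in 1 of 18, the chemokine CXCL8 from 11.3 ± 0.297 to 0.505 ± 0.0212 (adjusted p = 1.52e-07, and adjusted p = 0.193 with an estimated correlation). All 12 immediate early genes fell, DUSP6 by -2.19 ± 0.0774 (adjusted p = 1.32e-07, and adjusted p = 0.193 with an estimated correlation). Falls were also called for 10 of 13 glucocorticoid genes, with 1 rise (adjusted p = 7.42e-06, and adjusted p = 0.193 with an estimated correlation). The same held for 9 of 18 matrix genes, with 3 rises (adjusted p = 0.0102, and adjusted p = 0.462 with an estimated correlation), 10 of 17 cholesterol genes, with 3 rises (adjusted p = 0.0113, and adjusted p = 0.462 with an estimated correlation) and 19 of 20 ribosomal protein genes (adjusted p = 1.32e-07, and adjusted p = 0.459 with an estimated correlation). After quantile normalization 9 ribosomal protein genes fell and their median went from -0.38 to -0.11.

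Hypoxia and glycolysis genes rose in 14 and fell in 2 of 18, with hexokinase 2, HK2, up by 2.08 ± 0.0509 (adjusted p = 0.000392, and adjusted p = 0.459 with an estimated correlation). Interferon response genes rose in 12 and fell in 5 of 19, ISG15 from 8.98 ± 0.898 to 50.3 ± 0.29 (adjusted p = 0.031, and adjusted p = 0.462 with an estimated correlation). Aryl hydrocarbon receptor targets rose in 6 of 10 with none lower, and CYP1A1, the receptor's classical target, went from 6.34 ± 0.0141 to 27.4 ± 4.33 (adjusted p = 0.0337, and adjusted p = 0.481 with an estimated correlation). Without mono 2 the receptor list did not pass (adjusted p = 0.0766). NRF2 genes rose in 13 and fell in 2 of 19 (adjusted p = 0.0112, and adjusted p = 0.481 with an estimated correlation). Lists that did not pass included cell cycle genes (8 rises and 6 falls of 20, adjusted p = 0.831), neural markers (8 and 2 of 14, 0.362), mesenchyme markers (7 and 2 of 15, 0.162), airway genes (7 and 1 of 11, 0.304), lysosome genes (5 and 9 of 18, 0.127) and ER stress genes (12 and 5 of 19, 0.196). Adjusted over the list alone, counts differed by at most 2 from those over all genes in this comparison. Median, mean and test differed in sign for the WNT and p53 lists.

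The third comparison asked what nano carbon black changed, with v as the untreated set. Of 16 liver and gut markers 14 were higher in Carbon, as were 13 of 16 pan-epithelial genes, while of 19 interferon response genes 8 were lower and 2 higher. APOA2, a component of high-density lipoprotein, rose from 24.3 ± 9.25 to 179 ± 4.46 (log2 change 2.88 ± 0.192, adjusted p = 0.00013), and AFP, the fetal liver plasma protein, from 77.6 ± 14.1 to 251 ± 22.4 (1.69 ± 0.111, adjusted p = 0.00013). MX1, an interferon-induced antiviral protein, fell from 10.4 ± 0.276 to 4.75 ± 1.27 (0.458-fold, adjusted p = 0.00293). CYP1A1 was at 29.3 ± 4.21 in Carbon and 27.4 ± 4.33 in v, a 1.07-fold difference with a 95% interval of 0.874 to 1.30 that did not pass (adjusted p = 0.685). In all 918 of 13428 genes passed, 730 higher and 188 lower in Carbon, and 120 of them changed by at least 1 on the log2 scale. The share higher was 79.5%, against 89.5% after median-of-ratios scaling, 78.0% after quantile normalization and 64.1% as TPM. The 188 lower genes became 97 after median-of-ratios scaling and 348 as TPM. Leaving out v 2, Carbon 1, v 1 or Carbon 2 brought the count to 314, 357, 482 or 910, of which 16, 21, 45 or 90 were lower. Taking mono as the untreated set gave 6148 genes, of which 670 also passed against v, 585 of them in the opposite direction.

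Besides APOA2, the largest rises included those of APOA4 (2.59), the detoxifying enzyme GSTA1 (2.36), APOC3 (2.32), the intestinal retinol carrier RBP2 (2.32), APOB (2.10) and the drug-metabolizing CYP3A5 (2.07). Of these, APOA4 (-4.70), APOC3 (-4.67) and APOB (-2.60) were lower in v than in mono by more than they rose. APOA2 was higher in Carbon than in mono as well (3.05). After MX1 the largest falls were IFIT1 (-0.97), IFIT3 (-0.91), ISG15 (-0.71), DDR2 (-0.64), FOXB1 (-0.64), SLFN5 (-0.62) and IFI44L (-0.59). DDR2 lost its call without each of the 4 libraries in turn (adjusted p of 0.0738 to 0.229). Calls were also lost by ISG15 without v 1, v 2 or Carbon 1 (up to 0.0922), FOXB1 without v 2, Carbon 1 or Carbon 2 (up to 0.174), and SLFN5 and IFI44L without v 2 or Carbon 1 (up to 0.0663 and 0.0744).

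Liver and gut markers rose in 14 of 16 (16 adjusted over the list alone), APOB from 2.08 ± 0.0778 to 12.2 ± 0.799 and SERPINA1, antitrypsin, from 18.1 ± 7.13 to 69.9 ± 1.05 (camera adjusted p = 5.32e-22, and adjusted p = 0.405 with an estimated correlation). Pan-epithelial genes rose in 13 of 16 (14 adjusted over the list alone), with EPCAM at 156 ± 14.3 against 84.4 ± 8.68 and CLDN7 at 72.3 ± 13.2 against 37.7 ± 3.26 (adjusted p = 7.91e-15, and adjusted p = 0.437 with an estimated correlation). In mono these stood at 300 ± 3.18 and 120 ± 1.51, above Carbon. Against mono both lists turned lower in Carbon, with 5 rises and 9 falls of liver and gut markers (adjusted p = 0.158) and 0 rises and 12 falls of pan-epithelial genes (adjusted p = 3.7e-05, and adjusted p = 0.508 with an estimated correlation). AT1 markers rose in 4 of 14 (6 adjusted over the list alone): S100A6, GPRC5A, CLDN4 and IGFBP2, of which S100A6 changed by 0.77 ± 0.0908. The AT1 list had camera adjusted p = 0.000687, and adjusted p = 0.437 with an estimated correlation. The AT1 markers AGER (-0.23), PDPN (-0.11) and HOPX (0.01), named by rule in every comparison, did not pass. CLDN4 lost its call without v 1 or Carbon 1 (adjusted p of up to 0.0521) and IGFBP2 without each library in turn (0.135 to 0.229). Against mono the AT1 list was lower in Carbon, with 0 rises and 10 falls (adjusted p = 4.21e-06, and adjusted p = 0.176 with an estimated correlation). Lysosome genes rose in 6 of 18 (8 adjusted over the list alone), among them the glycosidases NEU1 (0.65 ± 0.0534) and GLA (0.84 ± 0.105), with adjusted p = 9.96e-06 and adjusted p = 0.405 with an estimated correlation. Cholesterol synthesis genes rose in 6 of 17 (11 adjusted over the list alone), INSIG1 by 0.49 ± 0.0642 (adjusted p = 2.7e-07, and adjusted p = 0.405 with an estimated correlation). As TPM 3 of them rose. Against mono neither lysosome (7 rises and 3 falls) nor cholesterol genes (3 and 5) passed, both at adjusted p = 0.734. The camera direction of the cholesterol list turned lower, but its median was -0.01 and its mean 0.03. Hypoxia and glycolysis genes rose in 5 and fell in 1 of 18 (7 and 1 adjusted over the list alone), LDHA by 0.66 ± 0.0773 (adjusted p = 0.000833, and adjusted p = 0.439 with an estimated correlation). Against mono 17 of them rose and 1 fell (camera adjusted p = 9.73e-09, and adjusted p = 0.149 with an estimated correlation). Of the lists called against v, only this one also passed against mono in the same direction. In v itself 14 of its genes were higher and 2 lower than in mono. Many of these calls depended on having both libraries of a group. A fit without 1 library leaves a lone library in a group, so lost calls do not show that a single library carried a rise. None of the named genes reversed in such fits. Without v 2 there were 4 pan-epithelial, 3 lysosome, 1 cholesterol and 1 hypoxia and glycolysis rises. Without Carbon 1 there were 2 AT1, 3 lysosome, 2 cholesterol and 2 hypoxia and glycolysis rises, and without v 1 there were 2 AT1 rises and 1 cholesterol rise.

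Interferon response genes fell in 8 and rose in 2 of 19 (9 and 3 adjusted over the list alone), IFIT1 from 5.59 ± 0.594 to 2.36 ± 0.29 (adjusted p = 0.00525, and adjusted p = 0.437 with an estimated correlation). IFIT1 in mono was at 0.59 ± 0.0707, below both. Falls numbered 5 without v 1, 5 without v 2, 4 without Carbon 1 and 7 without Carbon 2, with 1, 0, 0 and 1 rises. Against mono the list turned higher in Carbon, with 11 rises and 4 falls (adjusted p = 0.0608). NF-kB genes rose in 3 of 18 (4 adjusted over the list alone), the chemokine CCL20 by 1.45 ± 0.211 (adjusted p = 0.00782, and adjusted p = 0.48 with an estimated correlation), whereas CXCL8 was at 0.875 ± 0.403 against 0.505 ± 0.0212 (adjusted p = 0.292). Without Carbon 1 only 1 NF-kB gene rose. Against mono the NF-kB list was lower in Carbon, with 1 rise and 14 falls (adjusted p = 2.3e-08, and adjusted p = 0.149 with an estimated correlation). Matrix and TGF-beta response genes rose in 4 of 18 (5 adjusted over the list alone), among them CTGF (0.75 ± 0.0945) and TIMP1 (0.49 ± 0.05), with adjusted p = 0.0467 and adjusted p = 0.611 with an estimated correlation. Their median was -0.02, and 0.01 after median-of-ratios scaling, while their mean was 0.11. No ribosomal protein gene passed (4 rose adjusted over the list alone) although the list did (adjusted p = 1.24e-06, and adjusted p = 0.55 with an estimated correlation). Likewise 0 of 14 neural markers passed, with a list median of -0.20 (adjusted p = 0.0282, and adjusted p = 0.592 with an estimated correlation). Against mono, matrix genes (1 rise and 9 falls, adjusted p = 0.00501, and adjusted p = 0.501 with an estimated correlation) and ribosomal protein genes (0 and 13, adjusted p = 6.32e-06, and adjusted p = 0.501 with an estimated correlation) turned lower. Neural markers had 2 rises and 2 falls against mono, with a median of 0.10 (adjusted p = 0.899). The matrix list did not pass without v 1 (adjusted p = 0.0969) or Carbon 1 (0.209), nor did the neural list without v 2 (0.0903) or Carbon 1 (0.305).

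Against v, aryl hydrocarbon receptor targets had 0 risen and 1 fallen member of 10, in both counts: SLC7A5, at 36.3 ± 0.106 against 49.5 ± 1.46, which lost its call without each library in turn (adjusted p of 0.0743 to 0.18). Against mono the receptor list was higher in Carbon, with 4 rises and 0 falls (adjusted p = 0.0154, and adjusted p = 0.501 with an estimated correlation). AT2 markers were lower than in mono, with 2 rises and 11 falls (adjusted p = 1.15e-05, and adjusted p = 0.149 with an estimated correlation). NRF2 genes were higher than in mono, with 14 rises and 1 fall (adjusted p = 8.73e-05, and adjusted p = 0.492 with an estimated correlation). In v itself 13 NRF2 genes were higher and 2 lower than in mono. Against v, NRF2 genes had 2 rises of 19 (4 rises and 4 falls adjusted over the list alone), the transporter ABCC2 by 0.72 ± 0.103 and AKR1C1 by 0.46 ± 0.0664. HMOX1 was at 6.08 ± 0.17 in Carbon against 5.66 ± 0.00707 in v (adjusted p = 0.662). AT2 markers had 1 rise, CTSH (0.78 ± 0.0682), and 1 fall of 14, LAMP3 (-0.56 ± 0.104), which lost its call without v 1, v 2 or Carbon 1 (adjusted p of up to 0.111), and 3 and 3 adjusted over the list alone. No cell cycle gene of 20, p53 target of 17, heat shock gene of 12, metallothionein gene of 6, respiratory chain gene of 20, airway gene of 11, mesenchyme gene of 15 or pluripotency gene of 5 passed, in either adjustment. Among lists that did not pass as a whole, lung and foregut genes had 2 rises of 14, among them the endoderm factor GATA6 (0.81 ± 0.11), and phagocytosis genes had 1 rise of 15, the brush border protein VIL1 (0.83 ± 0.109). Further ones had 2 rises of 13 glucocorticoid genes, 3 of 19 fatty acid genes, 1 of 14 WNT genes, 1 of 12 immediate early genes, and 2 rises and 2 falls of 19 ER stress genes. Adjusted over the list alone these were 2, 2, 2, 4, 1, 2, and 2 and 4. Over all genes, counts fell to 0 for glucocorticoid genes without Carbon 1, for fatty acid and WNT genes without v 2, for immediate early genes without v 1, v 2 or Carbon 1, and for ER stress genes without v 1 or Carbon 1. Lung and foregut genes had 1 rise without v 1, v 2 or Carbon 1. Without Carbon 2 the lung and foregut (3 rises, adjusted p = 0.0127), immediate early (4 rises, 0.0495) and airway lists (1 rise, 0.0227) passed. Without v 1 the airway (0.0364) and respiratory chain lists (0.00888) passed, and so did the respiratory chain list without Carbon 1 (0.00675). Against mono, immediate early genes had 0 rises and 12 falls (adjusted p = 9.73e-09, and adjusted p = 0.149 with an estimated correlation), and glucocorticoid genes 1 and 11 (2.61e-07, and 0.125 with an estimated correlation). Lung and foregut genes had 4 and 5 against mono (0.0487, and 0.508 with an estimated correlation). Median, mean and test differed in sign for the matrix, glucocorticoid, fatty acid and cell cycle lists. EGFL7, an endothelial secreted factor, rose from 8.09 ± 0.665 to 16.9 ± 2.21 (adjusted p = 0.000696). CLDN5, the other tested endothelial marker, changed by -0.34 and did not pass over all genes. Against mono both endothelial markers were lower in Carbon. CD68, a lysosomal protein used as a macrophage marker, rose from 21.3 ± 0.58 to 58.4 ± 2.91 (1.41 ± 0.0558, adjusted p = 1.49e-05), while the other 2 tested blood markers did not pass. In v, CD68 lay below mono by more than this rise (log2 change -2.03).

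**Figure D3:**
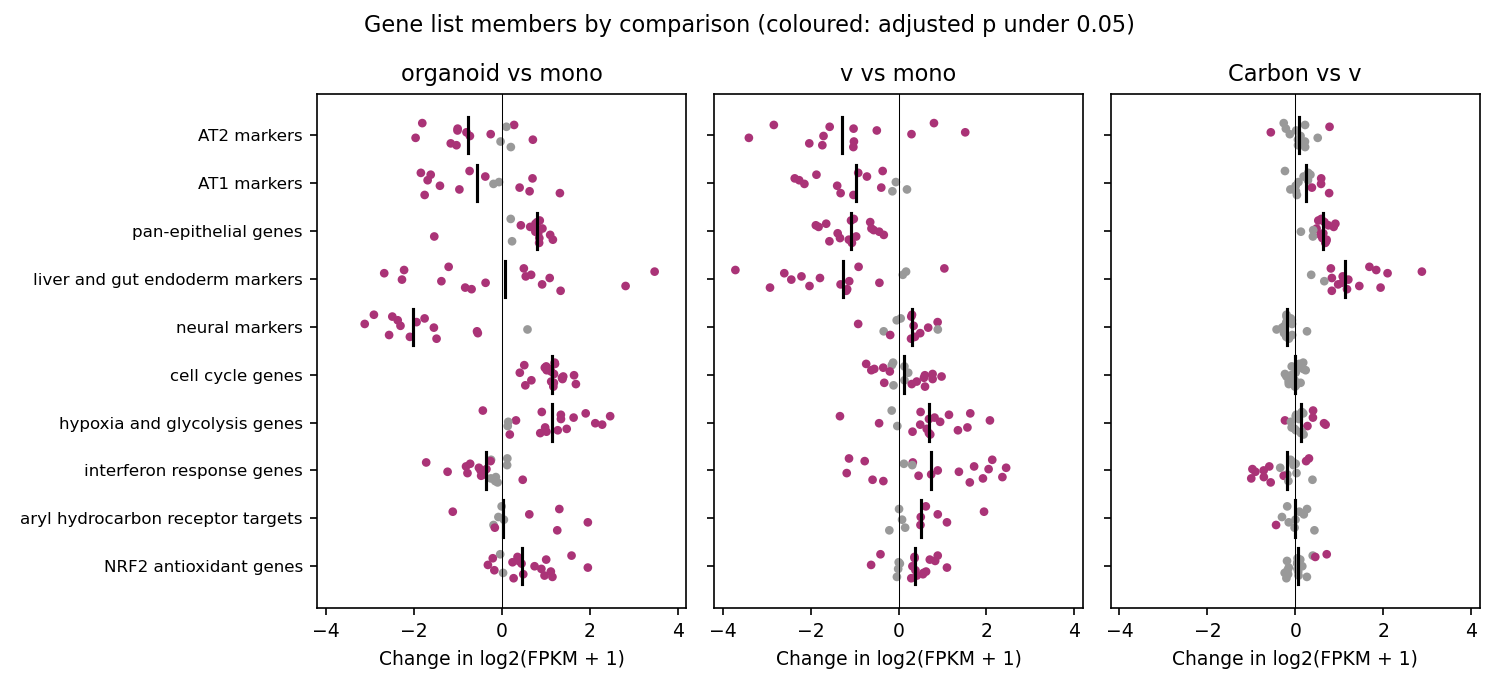
Change in log2(FPKM + 1) of each tested member of 10 gene lists in 3 comparisons, 1 point per gene, coloured where the limma adjusted p was under 0.05, with a black line at the list median. Points beyond the axis are not shown, among them PGC, an AT2 marker, in v against mono. Liver and gut markers lie mostly below 0 in v against mono and above 0 in Carbon against v, where the median was 1.13.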

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

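Fits that left out each library for lists and named genes were chosen after seeing the data, and the other alternatives before. Total counts stayed within 1.5 times the reported ones under every pseudocount, filter, scaling, trend and choice of fitted groups, but counts by direction did not. For Carbon against v the 188 lower genes became 116 and 105 with pseudocounts of 0.1 and 0.01, 121 without a filter, 97 after median-of-ratios scaling and 348 as TPM, and for organoid against mono the 3272 higher genes became 4917 after median-of-ratios scaling and 2042 as TPM. A log2 change of at least 1 left 1802 genes for organoid against mono, 120 for Carbon against v and 935 for v against mono, since it is stricter. Leaving out 1 library gave 314 (without v 2), 357 (without Carbon 1), 482 (without v 1) and 910 (without Carbon 2) genes for Carbon against v, of which 16, 21, 45 and 90 were lower in Carbon, where the lone library was assumed to vary like the other groups. The ranges were 8750 to 9219 for organoid against mono and 6021 to 6543 for v against mono. Of called named genes, 37 of 73 passed in every such fit of Carbon against v, 137 of 140 of organoid against mono and 125 of 130 of v against mono, and none reversed. The replicate block gave 9664, 842 and 7550 genes for organoid against mono, Carbon against v and v against mono and the same list counts. The numbers do not pair the libraries, since deviations of same-numbered libraries correlated at -0.06 (mono with organoid), -0.08 (v with Carbon) and 0.16 (mono with v).

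With mono as the control, Carbon gave 6148 genes, and with mono and v pooled 1342. Among lists called against at least 1 of v and mono, those that then turned lower in Carbon by the direction of camera, which ranks a list against other genes, were AT2 (adjusted p = 1.15e-05), AT1 (4.21e-06), lung and foregut (0.0487), pan-epithelial (3.7e-05), liver and gut (0.158), matrix (0.00501), glucocorticoid (2.61e-07), cholesterol (0.734), NF-kB (2.3e-08), immediate early (9.73e-09) and ribosomal protein genes (6.32e-06). Neural (0.899), aryl hydrocarbon receptor (0.0154) and interferon genes (0.0608) turned higher. Hypoxia and glycolysis (9.73e-09) and NRF2 genes (8.73e-05) kept their direction and passed as higher. Lists called against neither also changed sign, phagocytosis (0.228), WNT (0.994, with a median of 0.15) and metallothionein genes (0.734) to lower and mesenchyme (0.127), pluripotency (0.215) and ER stress genes (0.151) to higher. By the same rule, with v as the monolayer group AT2 (0.015) and AT1 genes (0.0297) turned higher in organoid. For matrix (0.437) and lysosome genes (0.719) the camera direction turned, while their medians stayed below 0, at -0.20 and -0.24, against -0.66 and -0.28 with mono. The lysosome mean went from -0.17 to 0.002. For organoid against mono itself, fry put airway (0.0397) and NF-kB genes (0.0252) lower, where camera had them higher. Over all alternatives the adjusted p of the called lists that turned ran from 7.66e-28 (liver and gut, Carbon against v) to 0.964 (aryl hydrocarbon receptor, Carbon against v). The cause of these turns was not tested beyond the distance between v and mono itself. Camera with an estimated correlation called 0 lists in each comparison (2, 3 and 5 at an unadjusted p under 0.05 for organoid against mono, Carbon against v and v against mono), and fry called 24, 4 and 22. With an estimated correlation camera had only 4 residual degrees of freedom, so its lack of calls decides little. The depth is unknown, so no lower limit of detection can be given.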

Other observations

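All tests in this part were chosen after the results were seen, except the fits with mono as the control and under other scalings. Changes from v to Carbon ran partly along those from mono to organoid, which share no libraries: across 13428 genes Pearson r was 0.318 and Spearman rho 0.392, and genes are not independent replicates. Of 721 genes called in both, 530 had the same direction. Rises in both numbered 394 against 178 for independent lists, and falls in both 136 against 91.2. APOA2 rose in both comparisons, but APOA4 (2.59 and -3.72) and APOB (2.10 and -2.68) rose in Carbon and fell in organoid. Liver and gut markers as a list rose in 14 of 16 in Carbon against v, but went 8 up and 8 down in organoid against mono.

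Against both untreated sets, 85 genes passed in the same direction, 71 higher and 14 lower in Carbon. Independent lists would give 194 and 36.0, and 20 simulations with no effect gave 0.05 genes on average. Both comparisons share the Carbon libraries, and v and mono themselves differ, so neither value is a fair reference, and the counts do not set an effect of treatment apart from variation between cultures. Among those higher were APOA2 (log2 change 2.88 against v and 3.05 against mono), AFP (1.69 and 0.78) and AKR1C1 (0.46 and 0.82), an aldo-keto reductase. AKR1C2 (0.65 and 0.78) and the squamous epithelial genes SPRR3 (1.08 and 1.11), KRT13 (0.75 and 1.26) and IVL (0.76 and 0.68) were picked after their values were seen. Against v, SPRR3 lost its call without v 1 or v 2, and KRT13 and IVL without v 1 or Carbon 1 (adjusted p of up to 0.073, 0.136 and 0.0633).

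Untreated v and mono libraries differed at more genes (7730) than Carbon and v (918). Scaling is argued against, since the smallest v against mono count under 3 other scalings was 7484, and so are single swapped libraries, since 8 of 8 libraries correlated best with their own group. Separate culture runs or media may lie behind the gap: 0 label fields other than the title differ, so runs cannot be told apart from the groups. A biological difference between the sets was not tested.

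Most liver and gut and pan-epithelial genes were higher in Carbon than in v. Scaling is argued against by a smallest liver and gut median of 1.16 under 3 other scalings. Whether a larger epithelial share was the whole cause of the liver and gut rise is not settled. Their median exceeded the pan-epithelial one by 0.502, which goes against it (permutation p = 0.00011, with genes treated as independent). The changes of the lists overlap, however, since the smallest liver and gut change was 0.364 and the pan-epithelial median 0.63. For the pan-epithelial genes a larger epithelial share may contribute, since 26 of 29 mesenchymal and neural members lay below 0, against 59.9% of other genes. Fisher's exact p was 0.000875, but it treats correlated genes as independent and does not measure variation between cultures. None of these members passed. Camera with an estimated correlation gave adjusted p = 0.855 for the mesenchyme list and 0.592 for the neural list. Variation between untreated cultures and an effect of nano carbon black cannot be told apart. Of the 27 risen members 81.5% had a Carbon mean within the range of the 4 untreated monolayer libraries, against 77.5% of other tested genes (Fisher's exact p = 0.818). With mono mirrored about v the share of members was 3.70%. That value was largely fixed beforehand, since members were chosen as higher in Carbon than v, and mono mostly lay above v for them. Of all called genes 95.9% moved toward mono. The simulated share with no effect, 66.7%, was taken over all genes rather than called ones, and v enters both differences. It is therefore not a fair reference, and a treatment that shifts cells toward mono would also give such movement.

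CYP1A1 was higher in Carbon than in mono, by 2.04 on the log2 scale (95% interval 1.75 to 2.33). Nano carbon black as the whole cause is argued against by a change of only 0.0936 from v to Carbon (-0.19 to 0.38). A condition shared by the v and Carbon cultures is a candidate explanation, as v lay above mono by 1.94 (1.66 to 2.23). What that condition was is not given in the sources used here.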
